A study of Mus musculus with 12 samples.

How the data were processed

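RNA sequencing libraries from 12 mouse brain tumours were analysed, with 3 libraries in each of 4 groups. The groups were taken from the labels: tumours of untreated young mice, of untreated old mice, of old mice given nicotinamide mononucleotide (NMN, a precursor of the coenzyme NAD) and of old mice joined to a partner by parabiosis, a surgical joining that lets both animals share a circulation. The labels describe 3 mice per group, and each library was treated as 1 mouse. The age of the parabiosis partner is not given in the sources used here. Young mice came from commercial breeders and old mice from an ageing colony, per the labels' protocols, so age and source cannot be separated. The labels give no sequencing batch.

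Per the labels' protocols, total RNA was extracted from the tissue, ribosomal RNA was depleted, and stranded libraries were sequenced as paired ends on an Illumina HiSeq instrument. Per the submitters' processing notes, the tools were FastQC, Bowtie2 2.1.0, RSEM 1.2.15 and edgeR, with the mm10 and GRCm38 builds. The authors deposited 1 table of CPM values scaled with TMM factors, with 24054 rows named by gene symbol, of which 3064 were at 0 in all 12 libraries. In 27 rows the symbol had been turned into a date; these were kept under the second name in the table and were not named in the text. RSEM shares reads between similar genes, so values of near-identical genes such as the haemoglobin and class I histocompatibility genes are uncertain.

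Within each library the deposited CPM values were whole multiples of the smallest value above 0 in 100% of cases at a tolerance of 0.01, which gave whole reads. The recovered totals ranged from 18566096 to 26779406 reads per library. A count of 3 reads corresponded to 0.100 to 0.143 CPM, which sets the limit of detection for counting error only. Count tests were run on these reads as alternatives chosen after seeing the data, and the main test used the CPM values because the table holds normalized values.

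CPM values were converted to log2(CPM + 1). Fold changes on this scale understate changes of genes with low values. Genes with a CPM of at least 1 in at least 3 of the 12 libraries were kept, which left 15232. All 12 libraries were fitted together with 1 mean per group in limma 3.58.1 (R 4.3.3) with a variance trend, and moderated test statistics were adjusted with the Benjamini-Hochberg method over all genes kept in each comparison. Genes were called at an adjusted p under 0.05, two-sided. The 3 main comparisons were old against young, NMN against untreated old, and parabiosis against untreated old. The 3 other pairs and an F test over the 4 groups were also run. p-values printed without another tool's name come from limma.

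A set of 33 gene lists for cell types, pathways and sample quality was fixed before the data were examined. Of the 507 list entries, 487 had a row, 4 of them under an older symbol. Lists with at least 3 genes kept, 30 in all, were tested with camera (limma) at its preset correlation between genes of 0.01 and adjusted over the lists. The list of mitochondrially encoded genes had 0 measured members and the lists for B and plasma cells and for muscle and skin had 2 each, so these 3 were not tested. Camera with an estimated correlation and fry were alternatives. A list score is the mean over its genes of the log2 deviation from the mean of the 12 libraries. The brain tissue score, or brain score, is the mean of the neuronal and myelinating oligodendrocyte list scores. As a covariate it takes out signal of these lists by construction, so their loss of a call there shows nothing.

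The rule for named genes was fixed together with the lists. It took called genes whose libraries did not overlap between groups and whose mean was at least 2 CPM in the higher group, up to 12 per direction in a main comparison and 5 in the others, ranked by log2 difference. Gene models without a name were left out. Where fewer than 5 genes qualified, the 5 with the smallest unadjusted p in that direction were given as values. Up to 4 members per list with the smallest p could be named, and 9 genes were always reported. A gene that this rule named is not reported here. The share of age-associated genes that moved back was planned on called genes, with the 200 genes of smallest unadjusted p in their place if fewer than 20 were called, and this second form applied.

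Because both treatments were compared with the same untreated old libraries, unchanged groups, with no age difference either, were simulated 100 times. Each simulated library was a normally weighted sum of the observed deviations from the group means. This form was added after an earlier one, which permuted the deviations between libraries, was seen to include draws in which the differences cancel, because deviations sum to 0 within a group. The earlier form was kept; its mean shares were 86.5% for NMN and 86.3% for parabiosis and its mean correlation was 0.47. Replicate pairs within groups had Pearson correlations of log2 values from 0.94 to 0.99, and the lowest chi-square per gene of any pair was 5.49, so no pair was as close as sampling noise alone.

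The tests were checked on simulated counts for the old against young comparison over 15232 genes. limma called 24 of 50 genes raised 2-fold, 19 of 50 lowered 2-fold, 42 of 50 raised 4-fold and 40 of 50 lowered 4-fold, and 10 unchanged genes. Simulated genes varied independently, which real tumours with varying tissue content do not. With no gene changed, 0 genes were called by limma and 0 lists by camera. Alternatives covered the pseudocount, the filter, the scaling, a replicate block, quality weights, fits of only 2 groups, each library left out, and the threshold. edgeR 4.0.16, DESeq2 1.42.0, a brain tissue covariate, leaving out 3 libraries with low Xist, and the list tests of the 3 other pairs were added after seeing the data. Gene positions are from the RefSeq annotation of GRCm38.p6, which matched 23868 rows (99.2%), 1326 of them by an older symbol. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.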

Results

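Brain tumours were grown by injecting mouse tumour cells, labelled as the line ms7080 although the protocol text names BC cells, into the striatum of female C57BL/6 mice, and tumour tissue was collected when the mice had symptoms. RNA was sequenced from 3 tumours of untreated young mice (2 months), 3 of untreated old mice (16 months), 3 of old mice given NMN at 300 mg per kg per day and 3 of old mice joined by parabiosis. The libraries held 18566096 to 26779406 recovered reads. The first principal component held 53.6% of the variance over 15232 genes and followed the score of a list of neuronal genes across the 12 libraries (Pearson r = 0.97, Spearman correlation 0.96, sign of the component arbitrary). Neuronal scores were lowest in young replicates 1 and 2, at -1.95 and -2.35, and highest in NMN replicate 1, at 1.76, and parabiosis replicate 3, at 1.43.

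The age comparison asked how tumours in old mice differ from tumours in young mice. Genes of neurons, myelinating oligodendrocytes and microglia, the resident immune cells of the brain, rose in tumours of old mice, as did genes of the extracellular matrix and of aged and disease-associated glia. Ribosomal protein genes and genes of oligodendrocyte precursors and proneural glioma fell. These 8 of 30 lists were called by camera at its preset correlation and 0 were called with an estimated correlation, where the adjusted p was 0.824 for each.

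All 16 measured neuronal genes had higher means in old mice, with a median log2 difference of 1.40 (camera adjusted p = 3.93e-09, adjusted p = 0.824 with an estimated correlation). Of these, 0 were called over all genes and 0 adjusted over the list alone. Young replicate 3 had a neuronal score of -0.21, above old replicates 2 and 3 at -0.31 and -0.50. The exact permutation p of the score was 0.3 on 3 against 3 libraries. The median was 0.96 without young replicate 2 and 1.94 without young replicate 3. Snap25, a synaptic vesicle fusion protein, averaged 221 ± 80.1 CPM in old and 108 ± 121.5 CPM in young tumours (SD, n = 3 each), a log2 difference of 1.57 ± 0.72 (SE). The 12 microglial genes were all above 0, with a median of 0.72 (adjusted p = 4.33e-07, adjusted p = 0.824 with an estimated correlation), and 0 were called over all genes against 4 adjusted over the list alone. P2ry12, a purinergic receptor of resting microglia, was at 10.7 ± 3.91 CPM against 4.28 ± 1.87 CPM, without overlap between the libraries, and Gpr34 at 7.23 ± 0.725 against 3.32 ± 0.468 CPM. Myelin genes had a median of 0.92 (adjusted p = 1.72e-06, adjusted p = 0.824 with an estimated correlation), 0 called over all genes and 6 adjusted over the list alone, among them Ugt8a, an enzyme of myelin lipid synthesis, at 7.02 ± 1.74 against 2.25 ± 1.02 CPM. The myelin median was 0.62 without young replicate 2 and 1.53 without young replicate 3.

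The 18 extracellular matrix genes had a median of 0.58 (adjusted p = 0.00161, adjusted p = 0.824 with an estimated correlation), with 0 called over all genes and 5 adjusted over the list alone. The fibrillar collagen gene Col1a2 averaged 81.6 ± 98.8 CPM in old against 6.34 ± 3.35 CPM in young tumours. Old replicate 1 had a matrix score of 1.43, and without it the list median was 0.23 (adjusted p = 0.0566); without old replicate 3 it was 0.99. The 22 ribosomal protein genes were all below 0, with a median of -0.19 (adjusted p = 2.06e-04, adjusted p = 0.824 with an estimated correlation; 0 called over all genes and 0 adjusted over the list alone). With quantile normalization this list had an adjusted p of 0.282, and its median was -0.11 without old replicate 1, -0.12 without young replicate 2 and -0.32 without young replicate 3. The 12 precursor genes were all below 0, with a median of -0.43 (adjusted p = 5.68e-04, adjusted p = 0.824 with an estimated correlation). Without young replicate 3 this median was -0.19 (adjusted p = 0.124), and without old replicate 3 it was -0.13 (adjusted p = 0.116). The 16 genes of aged and disease-associated glia (median 0.40, adjusted p = 0.0195) and the 14 proneural genes (median -0.18, adjusted p = 0.0492) had the same adjusted p of 0.824 with an estimated correlation. The glial list had a median of 0.084 without young replicate 3 (adjusted p = 0.307) and 0.14 without old replicate 2 (adjusted p = 0.376), against 0.74 without old replicate 3 and 0.70 without young replicate 1. The proneural list kept its call in 8 of 12 fits with a library left out, and its median was -0.079 without young replicate 3 (adjusted p = 0.505) and -0.078 without old replicate 1 (adjusted p = 0.307). It also lost its call without old replicate 2 (camera adjusted p = 0.0542) or NMN replicate 2 (camera adjusted p = 0.0512). Leaving out a library of neither group compared cannot change a log2 difference, so a call kept there shows little.

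No single gene passed in the age comparison in limma (0 of 15232) or edgeR (0), DESeq2 called 72, and 1060 genes had an unadjusted p under 0.05 in limma. Libraries of the groups did not overlap for 13.6% of genes, where chance gives 10%. The genes with the smallest unadjusted p did not pass (adjusted p = 0.590 for each). Slc6a11, a GABA transporter on chromosome 6 from 114131241 to 114249886, was 5.05 times as high in old tumours, at 19.01 ± 3.80 against 3.76 ± 1.75 CPM. Igfbp5, an insulin-like growth factor binding protein, averaged 614.7 ± 702.7 against 31.2 ± 9.85 CPM, with old replicate 1 at 1418 CPM. Lif, a cytokine, was at 2.17 ± 0.172 against 4.36 ± 0.222 CPM, and S100a10 at 23.9 ± 1.35 against 46.4 ± 10.9 CPM. The astrocyte gene Gfap was at 1517 ± 191 against 2450 ± 1001 CPM, Cdkn2a, a cell cycle inhibitor linked to senescence, at 36.7 ± 9.36 against 43.0 ± 5.75, Cdkn1a at 23.7 ± 3.84 against 31.5 ± 14.2, and the proliferation marker Mki67 at 606 ± 32.1 against 593 ± 164 CPM. Nampt, the rate-limiting enzyme of NAD salvage, was at 119 ± 9.32 against 113 ± 26.0 CPM, the T cell gene Cd8a at 2.17 ± 0.457 against 2.61 ± 0.429 and the myelin gene Mbp at 252 ± 41.0 against 173 ± 148 CPM. Quality weights in limma raised the count to 5453 genes, with weights from 0.225 to 8.55 and a fit that stopped short of convergence. Leaving out young replicate 3 gave 2 genes.

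**Figure D1:**
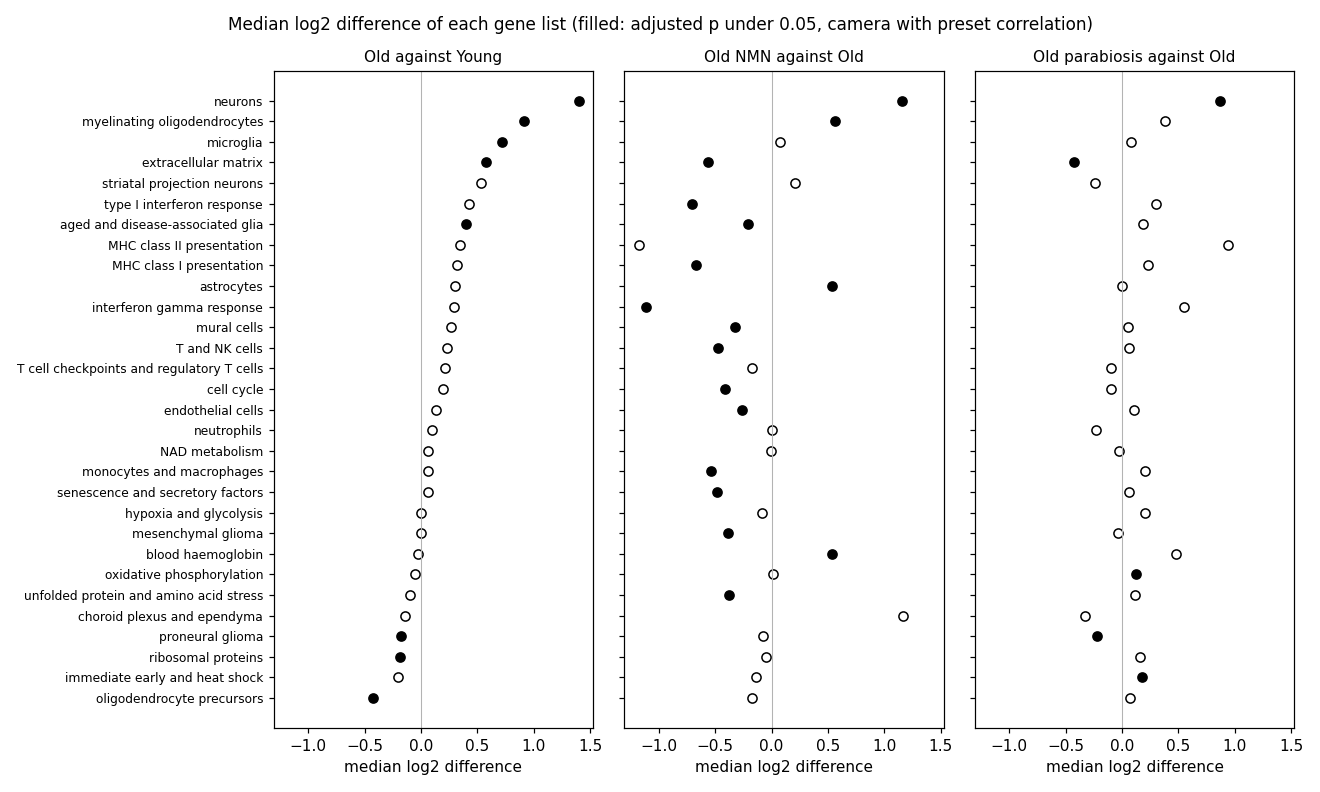
Median log2 difference of each of 30 gene lists (horizontal axis) in the 3 main comparisons, with lists ordered by the age comparison; filled circles are lists with an adjusted p under 0.05 by camera at its preset correlation. Neuronal genes lay at 1.40, 1.16 and 0.86 in the 3 comparisons, and 0 lists were called with an estimated correlation.

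The NMN comparison asked how the precursor changed tumours of old mice. Genes of the type I interferon response fell, as did genes of the interferon gamma response, the extracellular matrix, senescence and secretory factors, the unfolded protein response, mesenchymal glioma and the cell cycle. Neuronal, astrocyte, myelin and haemoglobin genes rose. Camera called 17 of 30 lists at its preset correlation, 4 up and 13 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.453. With a brain tissue score as covariate, chosen after seeing the data, 6 lists were called, 2 up and 4 down.

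All 20 type I interferon genes had lower means with NMN, with a median of -0.70 (adjusted p = 1.73e-06, adjusted p = 0.636 with an estimated correlation), and 0 were called over all genes or adjusted over the list alone. The median was -0.53 without old replicate 1 and -1.06 without old replicate 3. Rsad2, an antiviral enzyme, was at 24.5 ± 2.76 CPM with NMN against 45.8 ± 13.01 CPM in untreated old tumours. All 16 interferon gamma genes were lower, with a median of -1.12 (adjusted p = 1.41e-04, adjusted p = 0.636 with an estimated correlation); Gbp2, an interferon-induced GTPase, was at 47.9 ± 25.1 against 164 ± 93.2 CPM. Interferon gamma scores were 0.94 and 1.02 in old replicates 1 and 2, which had Xist near 0, and -1.32 in old replicate 3, against -1.17, -0.0038 and -1.60 with NMN (exact permutation p = 0.3, 3 against 3 libraries). The median was -0.73 without old replicate 2 and -1.79 without old replicate 3. Young replicate 3 also had Xist near 0, but its interferon gamma values were low for its group. Without it the interferon gamma median of NMN against young went from -0.77 to -1.53. High interferon gamma scores thus did not go with low Xist in every library. Of the 18 matrix genes 16 were lower, with a median of -0.56 (adjusted p = 3.10e-05, adjusted p = 0.636 with an estimated correlation), and Fn1, which encodes fibronectin, was at 251 ± 88.8 against 1241 ± 1130 CPM. Without old replicate 1, whose matrix score was 1.43 against 0.24 and 0.076 in the other old tumours, the matrix median was -0.34 (adjusted p = 0.00451). Of 17 senescence and secretory genes 15 were lower, with a median of -0.48 (adjusted p = 1.58e-04, adjusted p = 0.636 with an estimated correlation). Cdkn2a was at 20.3 ± 5.68 against 36.7 ± 9.36 CPM, a log2 difference of -0.84 ± 0.23 (SE, adjusted p = 0.480), and Cdkn2b at 3.90 ± 0.850 against 6.82 ± 1.37 CPM, while Cdkn1a was higher, at 36.3 ± 15.7 against 23.7 ± 3.84 CPM. In each of these lists 0 genes passed over all genes and 0 adjusted over the list alone.

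The 16 neuronal genes were all higher with NMN, with a median of 1.16 (adjusted p = 5.10e-06, adjusted p = 0.636 with an estimated correlation). The median was 0.73 without NMN replicate 1. Gad1, which makes the transmitter GABA, was at 138 ± 41.5 against 42.3 ± 17.1 CPM. Astrocyte genes had a median of 0.54 (adjusted p = 0.00106, adjusted p = 0.636 with an estimated correlation), with the gap junction gene Gja1 at 74.6 ± 4.28 against 35.3 ± 10.0 CPM, although Gfap was at 1135 ± 135 against 1517 ± 191 CPM. Of 25 cell cycle genes 23 were lower, with a median of -0.41 (adjusted p = 2.27e-04, adjusted p = 0.636 with an estimated correlation), and without NMN replicate 1 the median was -0.14 (adjusted p = 0.0785). Mesenchymal glioma genes (median -0.39, adjusted p = 3.69e-04, adjusted p = 0.453 with an estimated correlation) and unfolded protein genes (median -0.37, adjusted p = 1.41e-04, adjusted p = 0.636 with an estimated correlation) were lower for 15 of 17 and 16 of 16 members, and the unfolded protein median was -0.10 without NMN replicate 1 (adjusted p = 0.0393). The remaining called lists were T and NK cells (median -0.48), MHC class I presentation (-0.67), mural cells (-0.32), aged and disease-associated glia (-0.20), monocytes and macrophages (-0.54) and endothelial cells (-0.26), which fell, and myelin (0.56) and haemoglobin (0.54), which rose. Their adjusted p lay between 0.636 and 0.678 with an estimated correlation. Each of these last 8 lists had 0 genes called over all genes or adjusted over the list alone, and each lost its call in at least 1 of 12 fits with a library left out. Endothelial genes kept theirs in 5 of 12 and glial genes in 8. Glial genes lost theirs without old replicate 1, old replicate 2, NMN replicate 1 or NMN replicate 3, all from the groups compared. Leaving out a library of neither group cannot change a log2 difference, so a call kept there shows little. Without old replicate 1 the median was -0.068 for endothelial, -0.20 for mural, -0.42 for MHC class I and 0.88 for haemoglobin genes. Without old replicate 2 it was 0.014 for glial and -0.38 for MHC class I genes, and without old replicate 3 -0.52 for glial, -1.24 for MHC class I and -0.46 for endothelial genes. Without NMN replicate 1 it was -0.19 for monocyte and macrophage and 1.01 for haemoglobin genes, and without NMN replicate 2 -0.82 for monocyte and macrophage and -0.33 for glial genes. The 18 genes of NAD metabolism had a median of -0.0018 (adjusted p = 0.922), 9 above and 9 below 0.

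At the level of single genes limma called 0 with NMN, edgeR 0 and DESeq2 46, and 1573 had an unadjusted p under 0.05. The smallest adjusted p was 0.152, for Plekhg1, on chromosome 10 from 3740251 to 3967303, at 43.0 ± 4.74 against 18.4 ± 2.22 CPM and higher in 3 of 3 libraries. Others that did not pass (adjusted p = 0.480) were Kcnip1, a potassium channel partner, at 8.61 ± 1.62 against 1.95 ± 0.433 CPM, Tns1 at 93.4 ± 16.5 against 51.8 ± 8.31 CPM, and the tetraspanin gene Tspan6 at 50.3 ± 1.49 against 88.6 ± 20.8 CPM. Mki67 averaged 412 ± 128 against 606 ± 32.1 CPM, Nampt 94.2 ± 20.3 against 119 ± 9.32, Cd8a 1.97 ± 0.265 against 2.17 ± 0.457, P2ry12 12.5 ± 1.91 against 10.7 ± 3.91, Mbp 591 ± 287 against 252 ± 41.0 and Snap25 552 ± 387 against 221 ± 80.1 CPM.

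**Figure D2:**
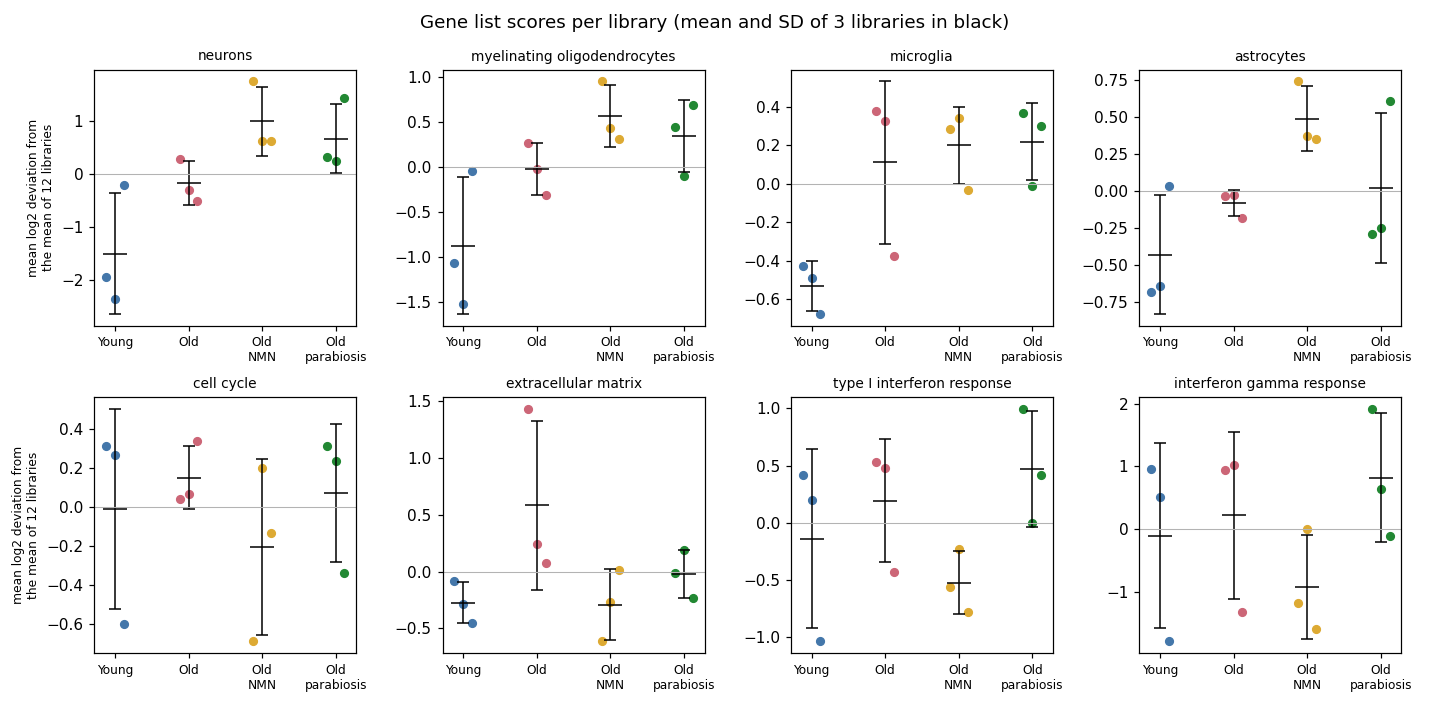
Score of 8 gene lists in each of the 12 libraries (vertical axis, mean log2 deviation from the mean of all libraries); points are libraries in order of replicate number, and black bars give the mean and SD of 3 libraries. Interferon gamma scores ranged from -1.79 to 0.96 within the young group and from -1.32 to 1.02 within the old group.

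The parabiosis comparison asked how sharing a circulation changed tumours of old mice. Neuronal genes, genes of oxidative phosphorylation and immediate early and heat shock genes rose, and genes of the extracellular matrix and of proneural glioma fell. These 5 of 30 lists were called by camera at its preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.893. With a brain tissue score as covariate, chosen after seeing the data, 15 lists were called, 11 up and 4 down.

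All 20 oxidative phosphorylation genes had higher means with parabiosis, with a median of 0.12 (adjusted p = 3.41e-04, adjusted p = 0.893 with an estimated correlation). Ndufb5, of respiratory complex I, was at 49.6 ± 2.71 against 41.4 ± 0.993 CPM. The 16 neuronal genes were all higher, with a median of 0.86 (adjusted p = 9.75e-05, adjusted p = 0.936 with an estimated correlation), and Nefh, a neurofilament gene, was at 11.4 ± 2.15 against 6.21 ± 0.988 CPM. The neuronal median was 0.42 without parabiosis replicate 3 (adjusted p = 0.0181). Immediate early and heat shock genes had a median of 0.18 (adjusted p = 0.00820), with Egr1 at 71.7 ± 28.1 against 41.3 ± 1.47 CPM; the adjusted p was 0.0574 without old replicate 1 and 0.0769 without parabiosis replicate 1, and the median was 0.38 without old replicate 2, 0.32 without parabiosis replicate 2 and 0.28 without parabiosis replicate 3. Matrix genes had a median of -0.43 (adjusted p = 0.00353), although Tnc, which encodes tenascin, was higher at 31.9 ± 11.4 against 14.5 ± 4.58 CPM, and without old replicate 1 the list median was -0.12 (adjusted p = 0.365). Proneural genes had a median of -0.22 (adjusted p = 0.0131), with Dcx, a gene of migrating neuroblasts, at 101.3 ± 34.5 against 187 ± 66.6 CPM. The proneural median was -0.038 without parabiosis replicate 3 (adjusted p = 0.409), -0.38 without parabiosis replicate 1 and -0.11 without old replicate 3 (adjusted p = 0.107). The immediate early, matrix and proneural lists had an adjusted p of 0.936 with an estimated correlation, and in all 5 lists 0 genes passed over all genes or adjusted over the list alone.

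No single gene passed with parabiosis in limma (0 of 15232) or edgeR (0), DESeq2 called 44, and 854 genes had an unadjusted p under 0.05 in limma. The smallest adjusted p was 0.701. Wnt3, a secreted signalling protein, was at 1.12 ± 0.129 against 3.06 ± 0.419 CPM. Among the 5 genes with the smallest p on the higher side, Eda, Prps1, Eif2s3x and Tsr2 lie on the X chromosome; Prps1 was at 74.2 ± 8.54 against 49.5 ± 1.19 CPM and Eif2s3x at 313.8 ± 19.9 against 225 ± 16.6 CPM. Cdkn2a was at 34.2 ± 4.36 against 36.7 ± 9.36 CPM, Cdkn1a at 26.3 ± 3.04 against 23.7 ± 3.84, Mki67 at 530.1 ± 193 against 606 ± 32.1, Gfap at 1460 ± 571 against 1517 ± 191, Nampt at 126 ± 19.4 against 119 ± 9.32, Cd8a at 2.58 ± 1.97 against 2.17 ± 0.457, P2ry12 at 10.4 ± 2.05 against 10.7 ± 3.91, Mbp at 358 ± 190 against 252 ± 41.0 and Snap25 at 425 ± 210 against 221 ± 80.1 CPM. With quality weights 516 genes were called.

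The comparison of NMN with young tumours was the one pair of 6 with genes called by limma, 1242 in all, of which 1084 rose and 158 fell. Of the 16 neuronal genes 15 rose over all genes tested and 16 adjusted over the list alone, with a median of 2.61 (camera adjusted p = 2.65e-10, adjusted p = 0.734 with an estimated correlation). Of 12 myelin genes 8 rose over all genes and 10 adjusted over the list alone (median 1.79, adjusted p = 0.734 with an estimated correlation), of 12 microglial genes 4 and 6 (median 0.75, adjusted p = 0.734 with an estimated correlation), and of 13 astrocyte genes 5 and 7 (median 0.78, adjusted p = 0.893 with an estimated correlation). The 6 lists that fell were interferon gamma (median -0.77), oligodendrocyte precursor (-0.58), unfolded protein (-0.43), type I interferon (-0.39), mesenchymal (-0.37) and ribosomal genes (-0.25), with camera adjusted p from 2.77e-04 to 0.0340 and from 0.734 to 0.893 with an estimated correlation. Of their genes only 3 mesenchymal ones were called lower over all genes. Neither interferon list was called without young replicate 1 (medians -0.26 and -0.070), young replicate 2 or NMN replicate 3. The precursor list lost its call without NMN replicate 2 or young replicate 3, and the ribosomal list without NMN replicate 1. With quantile normalization the camera adjusted p was 0.155 for type I interferon, 0.224 for interferon gamma, 0.108 for precursor and 0.155 for ribosomal genes. Median-ratio factors gave 0.0560 for interferon gamma. Without young replicate 3 the interferon gamma and type I medians were -1.53 and -0.83. The unfolded protein median was -0.22 without NMN replicate 1, and the ribosomal median -0.47 without NMN replicate 2. Slc6a11 rose from 3.76 ± 1.75 to 59.9 ± 19.4 CPM and Gja1 from 10.6 ± 3.84 to 74.6 ± 4.28 CPM (adjusted p = 0.0206 for each). Cdkn2a fell from 43.0 ± 5.75 to 20.3 ± 5.68 CPM (adjusted p = 0.0279), S100a10 from 46.4 ± 10.9 to 16.7 ± 3.78, Tnc from 30.0 ± 12.1 to 9.45 ± 4.24 and Has2, a hyaluronan synthase, from 44.9 ± 8.25 to 15.7 ± 6.89 CPM. The mesenchymal genes Lif, Stat3 and Cd44 also fell, Cd44 from 170 ± 21.9 to 86.4 ± 28.3 CPM. Quantile normalization called 734 higher and 336 lower genes, and DESeq2 1767 and 600. The count was 0 without young replicate 1, young replicate 2 or NMN replicate 3, 2 without NMN replicate 1, 478 without old replicate 2, 771 without parabiosis replicate 1, 1953 without parabiosis replicate 3, 2129 without young replicate 3, 93 in edgeR, 29 in a fit of the 6 libraries alone, 2367 in DESeq2 and 0 with a brain tissue score as covariate, chosen after seeing the data. With that covariate the median log2 difference of the higher genes went from 1.71 (median SE 0.378) to 0.33 (0.336), and that of the lower genes from -0.53 (0.125) to -0.41 (0.197). The F test over the 4 groups called 0 genes in limma, with 2780 at an unadjusted p under 0.05, 0 in edgeR and 1614 in DESeq2.

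Parabiosis against young gave 0 genes in limma, with 2763 at an unadjusted p under 0.05, 0 in edgeR and 977 in DESeq2, and 701 in limma without young replicate 3. Neuronal genes rose there too, with a median of 2.29 (camera adjusted p = 1.28e-11, adjusted p = 0.725 with an estimated correlation; 0 called over all genes and 16 adjusted over the list alone). NMN against parabiosis gave 0 genes in limma, with 1470 at an unadjusted p under 0.05, 0 in edgeR and 232 in DESeq2. The smallest adjusted p was 0.0842, for Wnt3, at 4.16 ± 0.428 with NMN and 1.12 ± 0.129 CPM with parabiosis, and for Tspan6, at 50.3 ± 1.49 and 107 ± 2.57 CPM.

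Whether the treatments moved age-associated genes back was examined on the 200 genes with the smallest unadjusted p in the age comparison, since 0 were called. With NMN 35.5% of them moved opposite to the age difference (exact binomial 95% interval 28.9 to 42.6%, genes taken as independent, which they are not). These were 34 of 148 genes higher and 37 of 52 genes lower in old tumours. With parabiosis the share was 43.5% (36.5 to 50.7%), 41 of 148 higher and 46 of 52 lower genes. The simulated unchanged groups held no age difference either, so they do not give the share to be expected where age does change genes. Low counts below therefore do not show that a treatment moved genes away from young. Compared with the same old libraries they gave mean shares of 86.9% and 83.3%, with ranges of 6 to 100% and 0 to 100%. Of 100 simulations 6 and 11 were at or below the observed shares. In the permuted form, which was run first, 4 and 2 of 100 were, and the parabiosis share lay below the 2.5th percentile of 46.2%. Without young replicate 3 the shares were 4.5% and 13%, and without old replicate 3 they were 69% and 77.5%. Across genes, which are not independent replicates, the NMN and parabiosis differences from untreated old correlated at r = 0.56, against a simulated mean of 0.47 (range -0.57 to 0.97). The covariance was 0.068 against a simulated 0.047, a difference of 0.021. The old libraries enter both differences, and 3 are too few to split between them. Without parabiosis replicate 3 the correlation was 0.11.

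**Figure D3:**
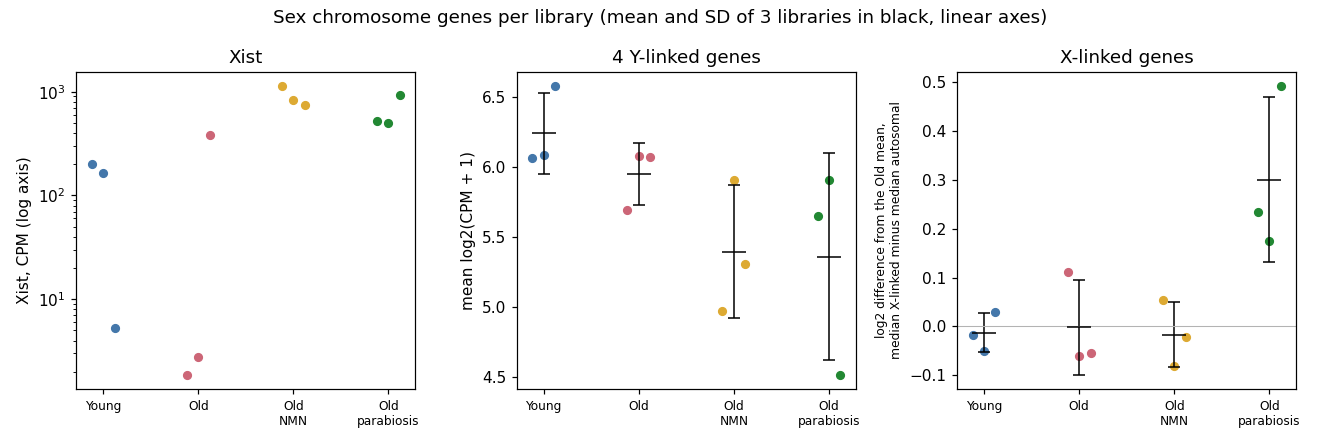
Xist in CPM on a log axis, the mean log2(CPM + 1) of 4 Y-linked genes, and the median log2 difference of X-linked genes from the old group mean relative to autosomal genes, for each of the 12 libraries; black bars in the second and last panels give the mean and SD of 3 libraries. Xist was at 5.33 CPM in young replicate 3 and at 1.88 and 2.76 CPM in old replicates 1 and 2, and at 164 to 1127 CPM in the other 9 libraries.

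Sex chromosome genes were read as a check of the labels, which give all mice as female. Xist, the RNA that silences one X chromosome in female cells (X chromosome, 103460373 to 103483233), was at 5.33 CPM in young replicate 3 and at 1.88 and 2.76 CPM in old replicates 1 and 2, and at 164 to 1127 CPM elsewhere. The Y-linked gene Ddx3y was present in all 12 libraries, at 34.0 to 132 CPM. Old replicates 1 and 2 belong to the untreated group that both treatments were compared with. Xist was at 742 to 1127 CPM with NMN and at 499 to 934 CPM with parabiosis. Both treatment comparisons were therefore confounded with whatever lowered Xist in these old tumours. Leaving out those 3 libraries left 1 untreated old library, too few to separate the 2.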

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

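The test with an estimated correlation below was chosen after the result was seen. A difference between the treatments led to a closer look at 19 gene lists, called by camera at its preset correlation in the direct comparison of NMN with parabiosis, both of which were compared with the same untreated old tumours. Type I interferon genes had a median log2 difference of -1.06 (adjusted p = 1.50e-10, adjusted p = 0.518 with an estimated correlation) and interferon gamma genes of -1.63 (adjusted p = 4.67e-08, adjusted p = 0.518 with an estimated correlation), the second at -1.03 without parabiosis replicate 1. MHC class II genes lay at -2.15, at -1.41 without NMN replicate 3 (adjusted p = 0.0531) and at -1.47 without parabiosis replicate 1 (adjusted p = 0.0559). Unfolded protein genes lay at -0.45, and at -0.23 without NMN replicate 1. The 2 lists higher with NMN were astrocyte genes, at 0.45 (0.19 to 0.71 with a library left out), and choroid plexus and ependymal genes, at 1.03. The choroid plexus value rested on NMN replicate 3, with a score of 3.15 against -0.34 and -0.41 in the other NMN tumours, and without it the median was 0.071 (adjusted p = 0.553); it was 1.72 without NMN replicate 1 and 1.57 without NMN replicate 2. With an estimated correlation 0 of these lists were called, and the adjusted p lay between 0.518 and 0.621.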

How the results depend on the processing

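edgeR, DESeq2, the brain tissue covariate, leaving out 3 libraries with low Xist and the list tests of the 3 other pairs were chosen after the result was seen. Of 6575 alternative values for named genes, 6176 kept their direction and side of the threshold. A further 223 lost a call, 132 gained one, 44 uncalled values changed sign and 0 called values reversed. In the 3 main comparisons 0 genes were called, so there a value that stayed uncalled shows little. Leaving out a library of neither group compared, or adding the replicate block, leaves the log2 difference as it was. In those settings a kept direction was fixed in advance. Without a filter on low values, NMN against young gave 742 genes, the F test over 4 groups 3, and the shares moved back were 47% for NMN and 54.5% for parabiosis; more genes were tested there. A pseudocount of 5 gave shares of 43.5% and 55.5%. Quantile normalization gave shares of 47% and 60%, 8 lists for parabiosis against old, and 1070 genes for NMN against young, of which 734 were higher and 336 lower. A replicate block gave 10 lists for parabiosis against old, and 0 genes and 20 lists for NMN against old. Deviations of same-number libraries correlated above 0.1 in 10 of 18 pairs (-0.50 to 0.60), including 3 of 3 for NMN and old (0.37, 0.21 and 0.31) and 3 of 3 for young and parabiosis (0.49, 0.39 and 0.56; with the block 0 genes and 10 lists, against 0 and 7), and 8 of 12 libraries correlated best with their own number; this is a hint from the data, as the labels give no pairing. Pairs with different numbers ranged as widely, from -0.64 to 0.59, with a median of -0.065 against 0.22 for same-number pairs. The other pairs of groups each mixed signs, such as -0.50, 0.60 and -0.064 for young and NMN. Quality weights, whose fit did not converge, gave 5453 genes for age, 516 for parabiosis against old, 2693 for NMN against young, 4448 for parabiosis against young, 6006 in the F test, and a share of 57.2% for parabiosis. Fits of only the 2 groups compared gave 29 genes for NMN against young, with fewer libraries to estimate the spread, and 9 lists for parabiosis against old.

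Camera with an estimated correlation called 0 lists in each of the 6 comparisons, and fry 0 in each. Mixed fry called 0 in the 3 main comparisons, 9 in NMN against young, 5 in parabiosis against young and 1 in NMN against parabiosis. A brain tissue score as covariate gave 1 gene for age, 0 for NMN against young and 110 for parabiosis against young, with 6 lists for NMN against old and 15 for parabiosis against old. Leaving out the 3 libraries with low Xist, which leaves 1 untreated old library taken to vary like the other groups, gave 2 genes for parabiosis against old, 327 for parabiosis against young, 2 for NMN against parabiosis and 11 in the F test, with 15, 9 and 17 lists in the age, NMN and parabiosis comparisons. edgeR gave 93 genes for NMN against young. DESeq2 gave 72 genes for age, 46 for NMN against old, 44 for parabiosis against old, 2367 for NMN against young, 977 for parabiosis against young, 232 for NMN against parabiosis and 1614 in its test over 4 groups. Where construction does not show it, the cause was not tested.

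Leaving out each library in turn gave 0 to 2 genes for age, 0 to 0 for NMN against old, 0 to 1 for parabiosis against old, 0 to 2129 for NMN against young, 0 to 701 for parabiosis against young, 0 to 1 for NMN against parabiosis and 0 to 689 in the F test. Lists ranged from 6 to 16 for age, 11 to 18 for NMN and 5 to 13 for parabiosis against old, the shares from 4.5 to 69% and from 13 to 77.5%, and the correlation of the treatments from 0.11 to 0.69. NMN against young gave 2129 genes without young replicate 3, 1953 without parabiosis replicate 3, 771 without parabiosis replicate 1, 478 without old replicate 2, 2 without NMN replicate 1, and 0 without young replicate 1, young replicate 2 or NMN replicate 3. Without young replicate 3 the F test called 689 genes, and without parabiosis replicate 3 it called 93. Depth limits single genes near 0.100 to 0.143 CPM, the value of 3 reads.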

Other observations

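The brain score as covariate, the 3 tests on Xist, and the camera, permutation and host tissue tests of X-linked genes were chosen after the result was seen. MHC class II genes differed widely within groups. H2-Aa, an antigen-presenting chain, was at 0.384 CPM in young replicate 3 against 116 and 108 CPM in the other young tumours, at 3.80 CPM in old replicate 3 against 93.0 and 119 CPM, and at 11.3 and 3.00 CPM in NMN replicates 1 and 3 against 62.8 CPM. Cd74, its invariant chain, followed, at 2.00 CPM in young replicate 3, 12.7 CPM in old replicate 3 and 532.6 CPM in parabiosis replicate 1. Ttr, a choroid plexus gene, was at 841 CPM in NMN replicate 3 and 115 CPM in young replicate 3, and at most 10.8 CPM in the other 10 tumours.

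Normal brain tissue in the libraries may account for most genes that rose in NMN against young. Of 1061 such genes outside the neuronal and myelin lists, 96.98% correlated positively with the brain score within groups, against 49.7% of all genes, and with the score as covariate the median log2 difference of all 1084 higher genes went from 1.71 to 0.33. The median of the 158 lower genes went from -0.53 to -0.41 while the median SE went from 0.125 to 0.197. Of these genes 67.1% correlated negatively with the score, where 49.7% of all genes correlated positively. Whether brain tissue accounts for part of them stays open, and their lost calls do not show that it does. Depth did not account for the total of 1242 calls, since thinning every library to the shallowest left 1295 genes called. Neither did scaling, with 1163 called under median-ratio factors. These are totals over both directions, and quantile normalization changed the split, so scaling stays open for the number of lower genes. A larger share of brain in these tumours could itself be an effect of age or treatment, or of where the tissue was cut, and 0 genes called with the covariate cannot separate these.

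Xist near 0 in 3 libraries labelled female could reflect host mice of the other sex. Y-linked genes could not decide this, since Y-linked RNA was present in all 12 libraries whatever their Xist level. In the other 9 libraries Y-linked values fell as the brain score rose (Spearman correlation -0.92, permutation p = 0.00136), and the 3 libraries lay 2.34, 0.48 and 1.04 residual SD above that line, the lowest being 0.484. The 3 libraries had brain scores of -0.13 (young replicate 3), 0.28 and -0.17 (old replicates 1 and 2). Young replicates 1 and 2 had lower brain scores, -1.51 and -1.94, yet Xist at 202 and 164 CPM. Old replicate 3 also had a lower score, -0.41, with Xist at 380 CPM. As far as the brain score follows host tissue, these values argue against female hosts in the 3 libraries. Few host brain cells did not account for the low Xist, since the lowest neuronal score of the 3 was 2.05 above the lowest of the others. Nor did depth, since 1 of the 3 had more reads than the median of the others.

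X-linked genes were higher in the 3 parabiosis tumours, by 0.23, 0.17 and 0.49 log2 units relative to autosomal genes and the old mean, over 431 genes with a mean of at least 5 CPM (camera p = 1.75e-35, p = 0.00985 with an estimated correlation, exact permutation p = 0.1 on 3 against 3 libraries, the smallest possible). A host tissue effect common to the groups did not account for it, since NMN tumours reached at most 0.053. Within the parabiosis group the shift was larger where the brain score was higher, with scores of 0.39, 0.078 and 1.06 in replicates 1 to 3. A host effect particular to this group thus stays open. After removal of a GC trend 103.1% of the shift was left. Single autosomes, measured in the same way, reached 0.153, 0.156 and 0.159 in parabiosis replicates 1 to 3. In young replicate 3 an autosome reached 0.319, above the X shift of parabiosis replicates 1 and 2. Shifts of that size thus also occurred off the X chromosome. A chromosome-wide gain in the tumour cells stays open: at least 78.9% of X-linked genes lay above old in each parabiosis tumour, but this share largely restates the shift, and old replicate 1 had 74.9%. DNA was not analysed here, and an effect of parabiosis itself was not tested.

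Other splits of the 6 libraries of a comparison were also tested, and 10 splits are too few for a share under 0.05. A real count of 0 is reached by any split, so the shares for such counts decide nothing. As many genes as the real 0 were called in 10 of 10 splits for age (highest other 1), and in 10 of 10 for NMN against old, parabiosis against old, parabiosis against young and NMN against parabiosis (highest other 0 each). NMN against young reached its 1242 genes in 1 of 10 splits, and the highest other had 871. As many lists as the real 8, 17 and 5 were called in 8 of 10 splits for age (highest other 18), 4 of 10 for NMN against old (highest other 21) and 10 of 10 for parabiosis against old (highest other 17, several times the real count, which points to a structure of the samples other than the groups). For the F test, 100 of 100 drawn splits called as many as the real 0, and the highest other called 68.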
